A study of Mus musculus with 8 samples.

How the data were processed

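RNA was measured in 8 libraries from 4 mouse pro-B cell lines of 129SV bone marrow origin, 2 libraries each from the WT line, CBE line 1, CBE line 2 and the Eµ-deleted line. Per the labels' protocols the cells were grown untreated in medium with serum, RNA was taken with the RNeasy Plus kit, and TruSeq stranded mRNA libraries were sequenced on a NextSeq 500 as single 75 bp reads with a target of 20 to 30 M reads. The submitters' processing notes name TopHat, Cufflinks and the mm9 build, and their versions and settings are not given in the sources used here.

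The deposited values are FPKM (fragments scaled by transcript length and by the number of mapped reads), with an interval and a quantification status for each gene, per the file headers. Each library had 24459 gene entries under 23929 symbols. For 277 symbols at several loci the FPKM were summed, and 21 symbols with a status other than OK in any library, among them Eef1a1, were left out. Coordinates are those of mm9 as the files give them. A GRCm38 annotation was used for GC content and transcript length by gene symbol only, and none of its coordinates were used. How reads on either strand were counted is not given in the sources used here, so values of genes with antisense neighbours, such as Hoxa11 and Hoxa11os, are uncertain.

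Read depth was not stated per library. The reads implied by each gene's interval, taken as 2 SD on each side of the value, summed to 49.5 and 33.1 M in WT, 43.4 and 31.3 M in CBE line 1, 33.0 and 35.5 M in CBE line 2, and 34.9 and 32.7 M in the Eµ-deleted line. Of low values, 67.2% implied a whole number of reads within 0.01, too few for a test on counts. A floor of 3 reads covers counting error only.

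Genes with FPKM of 1 or more in at least 2 of the 8 libraries were tested (10479 genes) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, as empirical Bayes moderated contrasts with a mean-variance trend, 4 residual and 2.65 prior degrees of freedom, and a spread shared by all 4 lines. Adjusted p-values are Benjamini-Hochberg values, with 0.05 as the threshold. The labels do not say that the libraries of a line came from separate cultures, so p-values measure the spread between libraries, which may be technical. A line left with 1 library in a leave-out fit was assumed to vary like the other lines. The comparisons were the CBE lines, jointly and singly, and the Eµ-deleted line against WT, CBE line 2 against line 1, and the Eµ-deleted line against the CBE lines.

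Of 27 gene lists fixed before the data were examined, 20 with at least 3 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. Camera compares a list with all other genes, and fry asks whether its members move one way on balance. The IgH constant, J, D and V lists, the V to D interval list and the stromal and mitochondrial lists had 0 measured members. The median, the mean and the camera direction did not all share a sign for the later B cell, tumour suppressor, interferon and cholesterol lists in the CBE lines against WT, the recombination, p53 and tumour suppressor lists in the Eµ-deleted line against WT, the early B, tumour suppressor, glycolysis, immediate early, sex-linked and housekeeping lists between the CBE lines, and the recombination, pro-B, myeloid and tumour suppressor lists between the Eµ-deleted and CBE lines. None of these was called by camera. Chromosomes were tested in the same way as lists, and so was the region near the IgH locus, as a single set per comparison. The p-values of that region are therefore unadjusted.

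Named genes followed a rule: in each of 3 main comparisons, the 8 largest rises and the 8 largest falls among called genes whose libraries did not overlap, passing over unnamed transcript models, up to 4 called members of each list, and always Rag1, Rag2, Ctcf, Pax5, Ebf1, Il7r, Trp53, Cdkn2a and Xist. The text names those of them whose calls held when any single library was left out, with exceptions stated, and 2 genes that the rule takes are not reported here.

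The lists, the naming rule, the comparisons and the alternatives were fixed before the data were examined, except the alternatives said to be chosen after seeing the data. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of 5 or more, median-of-ratios, TPM and quantile scaling, limma without the trend or with a robust prior, only the libraries compared, a replicate block, other quantification statuses kept, a fold change of 2 or more, and each library left out. Overlaps of calls were set beside 100 simulations of unchanged lines sharing the WT libraries. The test was tested on simulated data with independent normal noise and 200 changed genes among 10479, all of mean log2(FPKM + 1) above 2. For log2 changes of 0.5, 1 and 2 it recovered 29.9, 89.6 and 100% in the CBE comparison with WT with 7 false calls, 13.4, 83.6 and 100% in the Eµ comparison with 5, and 10.4, 85.1 and 98.5% between the CBE lines with 5. Recovery of genes with a lower mean was not examined, and fewer genes were changed there than were called in the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.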

Results

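Total RNA from 4 mouse pro-B cell lines was profiled by stranded poly(A) RNA-seq. Pro-B cells are the bone marrow B cell precursors in which the immunoglobulin heavy chain (IgH) locus is assembled by V(D)J recombination. The WT line is labelled WT, with no deletion named. A pair of lines (CBE line 1 and CBE line 2) had lost the CTCF-binding elements of IGCR1, the intergenic control region between the V and D segments of the locus, and the Eµ-deleted line had lost the intronic IgH enhancer. Each line gave 2 libraries, 8 in all, of 75 bp single reads. The read numbers implied by the deposited intervals were 31.3 to 49.5 M reads per library, highest in WT replicate 1. Expression was given as FPKM for 24459 gene entries per library, of which 9842 to 10082 had a value of 1 or more. Line values below are mean FPKM ± SD (n = 2), and fold changes are log2 differences of FPKM + 1, which understate the change of genes with low values.

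The libraries grouped by line. Libraries of the same line correlated with r of 0.978 to 0.992 across genes, and libraries of different lines with 0.926 to 0.964. The first principal component held 39.9% of the variance and placed both WT libraries apart from the 6 libraries of the 3 mutant lines. The next one, with 25.97%, separated the Eµ-deleted line from the CBE lines.

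**Figure D1:**
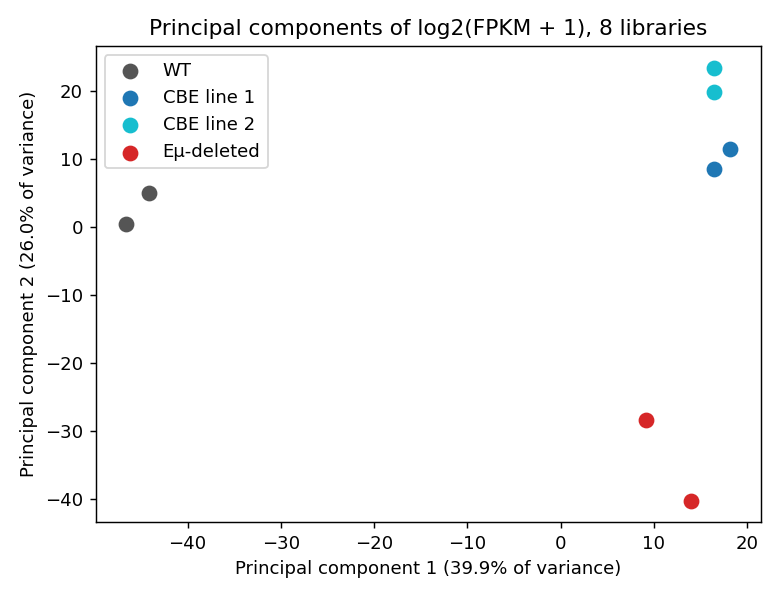
Each point is 1 library, placed by its scores on principal components 1 and 2 of log2(FPKM + 1) over the 10479 genes tested and coloured by line. The WT libraries lie at -44.12 and -46.61 on component 1, and the 6 libraries of the mutant lines between 9.15 and 18.21.

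At the IgH locus itself, no C, J, D or V gene symbol was among the genes analysed here, so the deleted elements could not be read from these values and the labels were not checked at the deleted sites. The exception was a pair of near-identical genes in the V to D interval, Adam6a and Adam6b (mm9 chromosome 12, 114782119 to 114784625 and 114727776 to 114730046), for which reads can be shared. Adam6b was listed at 0.0880 and 0.0921 FPKM in the WT libraries, 0.0576 and 0.0545 in CBE line 1, 0.107 and 0.123 in CBE line 2, and 0 in both Eµ-deleted libraries. For Adam6b, 3 reads were worth 0.0251 and 0.0264 FPKM in the Eµ-deleted libraries. Adam6a was listed at 0.0311 and 0.00751 in WT, 0.0172 and 0.0245 in CBE line 1, 0.0193 and 0.0178 in CBE line 2, and 0 in both Eµ-deleted libraries. These levels lie below the filter of 1 FPKM, and no test was made on them.

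Outside the V to C region, 31 expressed genes within 2 Mb of the Adam6 pair (mm9 chromosome 12, 112727776 to 116784625) were compared. Against WT, 7 were higher and 4 lower in the CBE-deleted lines (9 and 5 adjusted over the list alone), and 8 were higher and 2 lower in the Eµ-deleted line (9 and 2 adjusted over the list alone). Ckb, the brain-type creatine kinase, was at 0.0784 ± 0.0725 FPKM in WT, 2.66 ± 1.076 in CBE line 1, 1.19 ± 0.283 in CBE line 2 and 0.986 ± 0.317 in the Eµ-deleted line. Its call held in the CBE lines (adjusted p = 0.00285) in all 8 leave-outs, but in the Eµ-deleted line (adjusted p = 0.0343) it was lost without WT replicate 1 (adjusted p = 0.123) or 2 (0.170), CBE line 2 replicate 1 (0.0600) or 2 (0.0602), or Eµ-deleted replicate 1 (0.0984) or 2 (0.0592). It was also lost there with a pseudocount of 5 (0.124), no filter (0.0618) and quantile normalization (0.122). The gene Btbd6 was higher in the CBE lines by 1.58, adjusted p = 3.79e-05 and Crip2 by 1.45, adjusted p = 9.45e-05. In the Eµ-deleted line Btbd6 differed by -0.016 (limma adjusted p = 0.929) and Crip2 by 0.32 (0.0861). The proton-sensing receptor gene Gpr132 was lower in the CBE lines (log2 difference -0.90, adjusted p = 0.000491) and higher in the Eµ-deleted line (1.42, adjusted p = 0.000150). These 4 genes were chosen after their values were seen, as were those that follow. Called the same way in the CBE lines and the Eµ-deleted line were, among others, Rd3l (1.91 and 2.55), BC022687 (-1.09 and -1.60) and Nudt14 (-0.98 and -0.85). The calls of these further genes were not followed in the leave-outs. As a group the 31 genes were not called by camera in either comparison. For the CBE lines the median was 0.12 (camera unadjusted p = 0.384). For the Eµ-deleted line it was 0.20 (camera unadjusted p = 0.0607, or 0.141 with an estimated correlation). Without Eµ-deleted replicate 2 the latter median was 0.16, and on which side of the threshold this set fell depended on that library. The directional fry test, which does not compare the set with other genes, was past the threshold upward in both (unadjusted p = 0.0114 and 0.00469).

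The recombinase genes Rag1 and Rag2, whose products cut the IgH locus during V(D)J recombination, were higher in each mutant line than in WT. Rag1 (chromosome 2, 101478411 to 101489689 in mm9) was near 0 in WT, at 0.0427 and 0.0295 FPKM in the 2 libraries. It was at 13.8 and 7.41 in CBE line 1, 8.72 and 3.77 in CBE line 2, and 5.83 and 7.53 in the Eµ-deleted line. Rag2 (chromosome 2, 101464905 to 101472685) was at 0.0207 and 0.00543 in WT, 2.27 and 1.93 in CBE line 1, 3.07 and 1.98 in CBE line 2, and 3.96 and 5.38 in the Eµ-deleted line. The log2 rise of Rag1 was 3.07 (SE 0.33, adjusted p = 0.000876) in the CBE lines and 2.88 (SE 0.38, adjusted p = 0.00277) in the Eµ-deleted line, and that of Rag2 was 1.70 (SE 0.16, adjusted p = 0.000481) and 2.47 (SE 0.18, adjusted p = 0.000212). All 6 mutant libraries lay above both WT libraries for both genes. Genotype and cell line cannot be separated here, so a loss of these transcripts in the WT line cannot be told from a rise in the mutant lines. A further 28 genes, described below, were near 0 in the WT line alone. Between the CBE lines, Rag1 differed by -0.71 (SE 0.38, adjusted p = 0.332) and Rag2 by 0.17 (SE 0.18, adjusted p = 0.670), neither past the threshold.

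**Figure D2:**
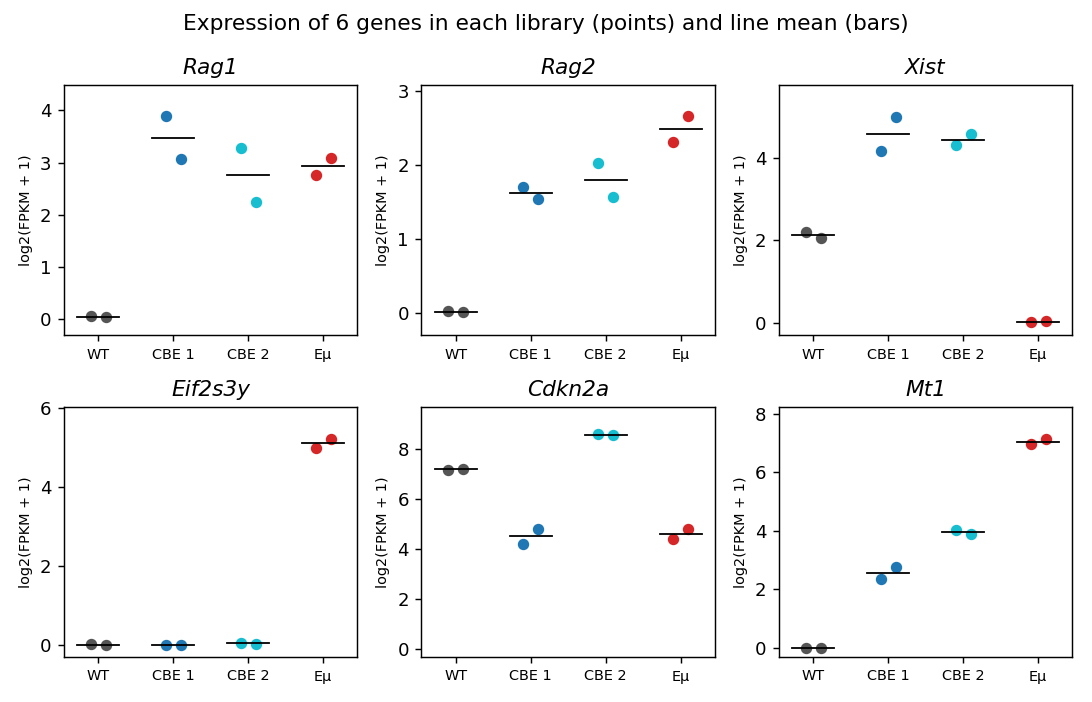
Points are the 2 libraries of each line and bars the line means, on a log2(FPKM + 1) axis, for Rag1, Rag2, Xist, Eif2s3y, Cdkn2a and Mt1. Rag1 and Rag2 lie near 0 in WT alone, Eif2s3y is above 0 in the Eµ-deleted line alone, and Cdkn2a is highest in CBE line 2.

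The comparison of the CBE-deleted lines with WT asks which transcripts differ between lines without the CTCF sites of IGCR1 and the single WT line. Cyp4f18, a cytochrome P450 of leukotriene breakdown, rose from 0.616 ± 0.283 FPKM in WT to 150.2 ± 14.5 in line 1 and 50.7 ± 0.478 in line 2, a log2 change of 5.78 (SE 0.21, adjusted p = 8.23e-06). Ngfrap1, an X-linked adaptor of the p75 neurotrophin receptor, rose from 0.00799 ± 0.0113 to 40.8 ± 3.63 and 62.8 ± 1.25. B4galnt1, a ganglioside synthase, rose from 0.0660 ± 0.0110 to 35.4 ± 14.4 and 47.4 ± 6.21. The other genes with the largest rises were Npepl1 (log2 5.25), Hmces, a sensor of abasic DNA sites (5.25), Fam92a (5.22), Tsnax (4.90) and Ctnna1, which encodes alpha-catenin (4.87), with adjusted p between 5.06e-07 and 3.30e-05. Apart from Cyp4f18, all of these rising genes are among the 28 described below that were near 0 in the WT line alone. They were expressed in the Eµ-deleted line as well, so their rises set the WT line apart and are not particular to the CBE deletion. In the other direction, Cyp2c55 fell from 78.0 ± 4.45 FPKM in WT to a listed 0 in all 4 CBE libraries. Gdpd3, a glycerophosphodiesterase, was at 83.3 ± 3.27 in WT and 0.126 ± 0.00554 and 0.109 ± 0.0203 in the CBE lines, a log2 change of -6.24 (SE 0.14, adjusted p = 1.81e-06). The melanocortin receptor gene Mc1r (-5.17), the chemokine receptor gene Ccr2 (-4.16), the transcription factor gene Sox15 (-3.97), Lgals3bp (-3.83), the osteopontin gene Spp1 (-3.53) and Rnase12 (-3.47) fell as well, with adjusted p up to 0.000702.

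In all, 2339 of 10479 genes differed between the CBE-deleted lines and WT, 1314 higher and 1025 lower, of which 448 and 255 changed at least 2-fold. Quantile normalization turned this balance, to 1142 and 1302. The joint test uses the spread between libraries and not that between the CBE lines, so it does not ask whether both lines changed alike. Taken line by line, CBE line 1 differed from WT in 2033 genes (1138 higher, 895 lower; 1023 and 1148 after quantile normalization) and CBE line 2 in 1960 (1102 higher, 858 lower; 1014 and 1198 after quantile normalization). The same direction was called in both lines for 1159 genes, 666 higher and 493 lower, and opposite directions for 39. Independent lists of these sizes would share 119.7 higher and 73.3 lower genes. Simulated lines with no effect that share the WT libraries shared 0.02 on average over 100 simulations. No gene was changed in those simulated lines, so they had few calls to share by construction and cannot gauge an overlap of lists this long. The WT group has only 2 libraries and was not split, so part of the excess over independent lists may come from the shared controls. A change in the WT line alone would add to it too. The covariance of the log2 changes of lines 1 and 2 was 0.326, against 0.0211 in the simulation, and their correlation 0.74 against 0.50. A change in the WT line alone would raise the covariance. The count depended on single libraries, falling to 1151 without WT replicate 1, 1022 without WT replicate 2, 1471 without CBE line 2 replicate 1 and 1463 without CBE line 2 replicate 2. The count for line 1 was 1034 and 903 without WT replicate 1 or 2, and that for line 2 was 1037, 975, 956 and 950 without WT replicate 1, WT replicate 2, CBE line 2 replicate 1 or CBE line 2 replicate 2. Without the same 4 libraries the 1159 shared calls were 611, 550, 647 and 655. WT is represented by 1 cell line, so genotype and line cannot be separated here.

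Among the early B lineage transcription factors, 7 of 26 rose and 1 fell (8 and 2 adjusted over the list alone). Id3, an inhibitor of E proteins, rose from 36.4 ± 2.98 FPKM to 88.0 ± 11.96 in line 1 and 89.2 ± 9.41 in line 2, and Gfi1, a zinc finger repressor, from 0.441 ± 0.0566 to 3.02 ± 0.0794 and 1.34 ± 0.128. Pax5 and Ebf1, which set and hold B cell identity, showed log2 differences of 0.47 (SE 0.14, adjusted p = 0.0572) and 0.19 (SE 0.13, adjusted p = 0.346), and the interleukin 7 receptor gene Il7r one of 0.25 (SE 0.33, adjusted p = 0.655). Leaving aside the fit with the replicate number, Pax5 passed the threshold without CBE line 1 replicate 1 (adjusted p = 0.0439), Eµ-deleted replicate 1 (0.0241) or Eµ-deleted replicate 2 (0.0240). It also passed with median-of-ratios scaling (0.0466) and with only the libraries compared (0.0240). Of the pro-B and pre-B surface and signalling genes, 6 of 28 rose and 2 fell (11 and 2 adjusted over the list alone). For later B cell and antigen presentation genes, 3 of 16 rose and 2 fell (3 and 2 adjusted over the list alone), with Xbp1, a transcription factor of plasma cells, at -2.03, the syndecan gene Sdc1 at 2.01 and the class II gene H2-Ab1 at 1.80 on the log2 scale. V(D)J recombination and end joining factors contained 2 rises, Rag1 and Rag2, and 1 fall among 23 members (2 and 1 adjusted over the list alone). Of the CTCF, cohesin and looping factors, 3 of 22 rose and 0 fell (3 and 0 adjusted over the list alone), and Ctcf itself differed by 0.23 (SE 0.13, adjusted p = 0.264). None of these 5 lists was called against other genes for the mean of the CBE lines (camera adjusted p = 0.178 to 0.978). For line 1 alone the pro-B and pre-B list was called, with 11 higher and 2 lower (12 and 2 adjusted over the list alone; median 0.32; camera adjusted p = 0.00969; adjusted p = 0.930 with an estimated correlation). For line 2 it was at camera adjusted p = 0.790 with 4 higher and 3 lower (4 and 3 adjusted over the list alone).

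Proliferation genes lay higher in the CBE lines: 8 of 29 rose and 0 fell (9 and 0 adjusted over the list alone). Their median log2 difference was 0.34 (camera adjusted p = 0.00452, or 0.992 with an estimated correlation). The directional fry test did not pass the threshold for this list (adjusted p = 0.133), nor for the histone genes below (0.0600). Ccne1, a G1/S cyclin, rose by 0.61 (SE 0.08, adjusted p = 0.00168). This list was not called without WT replicate 2 (median 0.27, adjusted p = 0.0537). Among replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, 9 of 56 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.0108; adjusted p = 0.992 with an estimated correlation), but the median was -0.15 when genes of mean FPKM 5 or more were kept. By line, 25 histone genes rose in CBE line 1 (34 adjusted over the list alone; median 0.76; camera adjusted p = 1.53e-06; adjusted p = 0.557 with an estimated correlation). In CBE line 2, 0 were called by limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05; median 0.03; camera adjusted p = 0.790 in the downward direction). In the glycolysis and hypoxia list, 6 of 24 rose and 0 fell (6 and 0 adjusted over the list alone), among them the mitophagy gene Bnip3 (1.44) and the hexokinase gene Hk1 (1.15), with camera adjusted p = 0.0869. T lineage markers moved mostly down: 1 of 7 rose and 4 fell (1 and 4 adjusted over the list alone), with Cd28 at -2.16, Cd5 at -1.43, the adaptor gene Lat at -1.14 and Tcf7 at 1.97 (camera adjusted p = 0.0869; the directional fry test gave an adjusted p = 0.00588). Markers of other lineages were few: in the myeloid list 1 of 5 rose and 0 fell (1 and 0 adjusted over the list alone), the single measured erythroid gene, Car2, differed by 0.65 (SE 0.09, adjusted p = 0.00224), and of the 2 measured NK genes, Klrd1 was at 1.07 and Klrb1c at -0.83.

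Of the remaining lists, interferon response genes went both ways: 7 of 30 rose and 4 fell (7 and 4 adjusted over the list alone), with Gbp2 at 1.72, Oas1a at -1.93, Iigp1 at -1.45 and Gbp6 at -1.28. For immediate early and NF-kB genes, 6 of 23 rose and 3 fell (8 and 4 adjusted over the list alone), with Jun at 2.43 and the chemokine gene Ccl3 at -2.36. In the adhesion and migration list, 7 of 18 rose and 3 fell (8 and 4 adjusted over the list alone), with the receptor genes Cd97 (2.67) and S1pr1 (2.52) up and the integrin gene Itga5 (-1.93) down. By line, this list had 8 higher and 2 lower in line 1 (10 and 3 adjusted over the list alone, median 0.70). It was not called by camera there (adjusted p = 0.0669, or 0.557 with an estimated correlation), while fry went upward (adjusted p = 0.00611). In line 2 it had 2 higher and 5 lower (4 and 6 adjusted over the list alone, median -0.01). Camera did not call it there either (adjusted p = 0.784), while fry went downward (adjusted p = 0.0115). Of STAT5 and JAK targets, 5 of 20 rose and 2 fell (5 and 2 adjusted over the list alone), with Il2ra at 1.78. Of p53 targets, 2 of 20 rose and 4 fell (2 and 5 adjusted over the list alone), with Pmaip1, a BH3-only gene, at 2.79 and Phlda3 at -1.80, and Trp53 itself at 0.09 (SE 0.07, adjusted p = 0.388). Among tumour suppressors often lost in transformed lines, 1 of 7 rose and 2 fell (1 and 2 adjusted over the list alone), with Cdkn2b at -2.01. The other fall was that of Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, at -0.64 (SE 0.18, adjusted p = 0.0462) for the mean of lines that went opposite ways. It fell in line 1 (-2.67 (SE 0.21, adjusted p = 0.000260)) and rose in line 2 (1.39 (SE 0.21, adjusted p = 0.00454)). The joint call was lost without WT replicate 1 (adjusted p = 0.205) or 2 (0.226), CBE line 1 replicate 1 (0.0529), or CBE line 2 replicate 1 (0.116) or 2 (0.126). It was also lost with no filter (0.0744), with mean FPKM of 5 or more (0.0575) and with TPM (0.0644). For integrated stress response genes, 2 of 24 rose and 1 fell (2 and 1 adjusted over the list alone). Cholesterol genes (23 measured) and housekeeping genes (15 measured) had 0 calls by limma, also with 0 adjusted over the list alone, and 1 and 2 members at an unadjusted p under 0.05. In the sex-linked list 1 of 5 rose, Xist, also adjusted over the list alone. For the mean of the CBE lines, the smallest camera adjusted p among these lists was 0.237.

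Loss of the intronic enhancer was examined in the Eµ-deleted line against WT. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, were listed at 0 in both WT libraries and at 132 ± 10.9 and 44.2 ± 7.53 FPKM in the Eµ-deleted line. In the CBE lines Mt1 stood at 4.99 ± 1.16 and 14.6 ± 1.04. Crhbp, the corticotropin-releasing hormone binding protein, rose from 1.00 ± 0.0431 to 104 ± 28.1, and the X-linked lymphocyte gene Xlr from a listed 0 to 49.5 ± 11.9. B4galnt1, the corepressor gene Aes, Ngfrap1 and Npepl1 rose by 5.49, 5.32, 5.26 and 5.25 on the log2 scale. Of these, B4galnt1, Ngfrap1 and Npepl1 were near 0 in the WT line alone. Enpep, the aminopeptidase known as the BP-1 antigen of B cell precursors, fell from 172 ± 2.43 to 1.59 ± 0.577 FPKM, a change of -6.08 (SE 0.15, adjusted p = 2.52e-06). Nov, a matricellular protein gene (-5.12), Gfra1, a GDNF receptor gene (-5.05), Cyp2c55 (-5.03), Akr1c12 (-4.26), Rnase12 (-4.08), the neurexin gene Nrxn2 (-3.96) and Ccr2 (-3.96) fell too, with adjusted p up to 0.00204.

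The Eµ-deleted line also differed from all others in sex-linked transcripts. The Y genes Eif2s3y, Ddx3y, Kdm5d and Uty were at 33.6 ± 3.94, 16.7 ± 3.54, 7.37 ± 1.05 and 5.61 ± 1.75 FPKM there and at 0.0275 or less as line means elsewhere. Xist, the RNA that silences an X chromosome in female cells, was at 0.00569 and 0.0259 FPKM in the Eµ-deleted libraries, 3.62 and 3.19 in WT, 17.02 and 30.9 in CBE line 1, and 18.99 and 22.8 in CBE line 2. Its log2 difference from WT was 2.38 (SE 0.22, adjusted p = 0.000453) in the CBE lines and -2.12 (SE 0.25, adjusted p = 0.00182) in the Eµ-deleted line. With a pseudocount of 5 the latter had an adjusted p = 0.0507. All 5 measured sex-linked genes were called in the Eµ-deleted line, 4 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00260; adjusted p = 0.896 with an estimated correlation). Every comparison with this line therefore also compares libraries with and without Y transcripts.

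In the Eµ-deleted line 2284 genes differed from WT, 1189 higher and 1095 lower, with 433 and 318 at least 2-fold. This balance turned after quantile normalization (1143 and 1279), with no filter (1305 and 1453) and without Eµ-deleted replicate 2 (742 and 822). A single direction was called in all 3 mutant lines for 842 genes, 467 higher and 375 lower, against 13.6 and 7.66 from independent lists and a mean of 0 in the simulation with shared WT libraries. These are the genes in which the WT line stood apart from each other line, so a change in the WT line alone would give the same set. Neither comparator tells such a change from changes shared by the mutant lines. The simulated lines held no changed genes, so their mean of 0 was set by construction. Log2 changes of the Eµ-deleted line and of the CBE lines had a covariance of 0.289, against 0.0209 simulated, and a correlation of 0.70 against 0.58. As above, the WT libraries were not split, so part of the excess may come from the shared controls. A change in the WT line alone would raise the covariance too. The count for the Eµ-deleted line was 999 and 890 without WT replicate 1 or 2, and 1513 and 1512 without CBE line 2 replicate 1 or 2. The 842 shared calls were 408, 362, 466 and 469 without the same libraries.

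Early B lineage transcription factors lay higher in the Eµ-deleted line: 7 of 26 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0291; adjusted p = 0.896 with an estimated correlation). Gfi1 rose by 2.46 and Ikzf3, which encodes Aiolos, by 1.07, while Ebf1 rose by 0.71 (SE 0.15, adjusted p = 0.0174) and Pax5 differed by 0.56 (SE 0.16, adjusted p = 0.0525). Ebf1 was not called without WT replicate 1 (adjusted p = 0.0918), WT replicate 2 (0.108) or Eµ-deleted replicate 2 (0.0736). Of pro-B and pre-B surface and signalling genes, 7 of 28 rose and 3 fell (10 and 3 adjusted over the list alone) (median 0.29; camera adjusted p = 0.0486; adjusted p = 0.896 with an estimated correlation), among them Arpp21 at -1.81, and Il7r differed by 0.76 (SE 0.38, adjusted p = 0.206). Leaving aside the fit with the replicate number again, Pax5 passed the threshold without CBE line 1 replicate 1 (0.0452) or 2 (0.0449) or Eµ-deleted replicate 1 (0.0159). It also passed with median-of-ratios scaling (0.0411) and with TPM (0.0452). Of looping factors, 2 of 22 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0486; adjusted p = 0.896 with an estimated correlation), and Ctcf differed by 0.38 (SE 0.15, adjusted p = 0.115). Of proliferation genes, 5 of 29 rose and 0 fell (5 and 0 adjusted over the list alone). Their median was 0.23 (camera adjusted p = 0.0291, or 0.896 with an estimated correlation). The directional fry test did not pass the threshold for the early B, pro-B or looping lists (adjusted p = 0.0917 each) or for proliferation genes (0.302). None of these 4 lists was called without WT replicate 2 (adjusted p = 0.0579, 0.254, 0.0579 and 0.115 in the order given), and looping factors also lost the call without WT replicate 1 (0.0940), CBE line 2 replicate 1 (0.0522) or 2 (0.0521) or Eµ-deleted replicate 2 (0.140). Early B factors were at 0.140 without Eµ-deleted replicate 2, pro-B genes at 0.0520 without CBE line 2 replicate 1 or 2, 0.0855 without Eµ-deleted replicate 1 and 0.112 without replicate 2, and proliferation genes at 0.523 without Eµ-deleted replicate 1.

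T lineage markers were mostly lower in the Eµ-deleted line as well. Of these markers, 1 of 7 rose and 4 fell (1 and 4 adjusted over the list alone), among them Cd28 (-2.47), the kinase gene Lck (-1.71), Cd5 (-1.38) and Tcf7 (1.74), at camera adjusted p = 0.106 and fry adjusted p = 0.00353. Among later B cell genes, 2 of 16 rose and 4 fell (2 and 4 adjusted over the list alone), with H2-Ab1 at 3.76 and Sdc1 at 1.96. In the recombination list, 2 of 23 rose and 2 fell (2 and 1 adjusted over the list alone). Of interferon genes, 3 of 30 rose and 7 fell (4 and 8 adjusted over the list alone), among them Iigp1 (-1.51) and Gbp6 (-1.31). In the adhesion list, 8 of 18 rose and 2 fell (8 and 2 adjusted over the list alone), with Cd97 at 3.41 and Anxa1, which encodes annexin A1, at -2.71. For immediate early genes, 7 of 23 rose and 4 fell (9 and 4 adjusted over the list alone), with Jun at 2.65, and for STAT5 targets, 6 of 20 rose and 1 fell (6 and 1 adjusted over the list alone), with Stat5b at 0.88 and Il2ra at 1.56. Of p53 targets, 2 of 20 rose and 4 fell (3 and 5 adjusted over the list alone), with Pmaip1 at 2.58, and Trp53 at 0.17 (SE 0.08, adjusted p = 0.180). Cdkn2a was the only tumour suppressor of 7 called, also adjusted over the list alone, and fell by 2.58. The stress list (2 higher, 0 lower; 2 and 0 adjusted over the list alone), glycolysis list (1 and 1; 1 and 0), histone list (3 and 0; 0 and 0), housekeeping list (1 and 0; 0 and 0), cholesterol list and myeloid list (0 and 0 by limma, and 0 adjusted over the list alone) had few calls. At an unadjusted p under 0.05 the latter lists had 1 and 1. The camera adjusted p of these lists other than T lineage lay between 0.0852 and 0.974. Car2 differed by 1.58 and Klrb1c by -0.86.

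**Figure D3:**
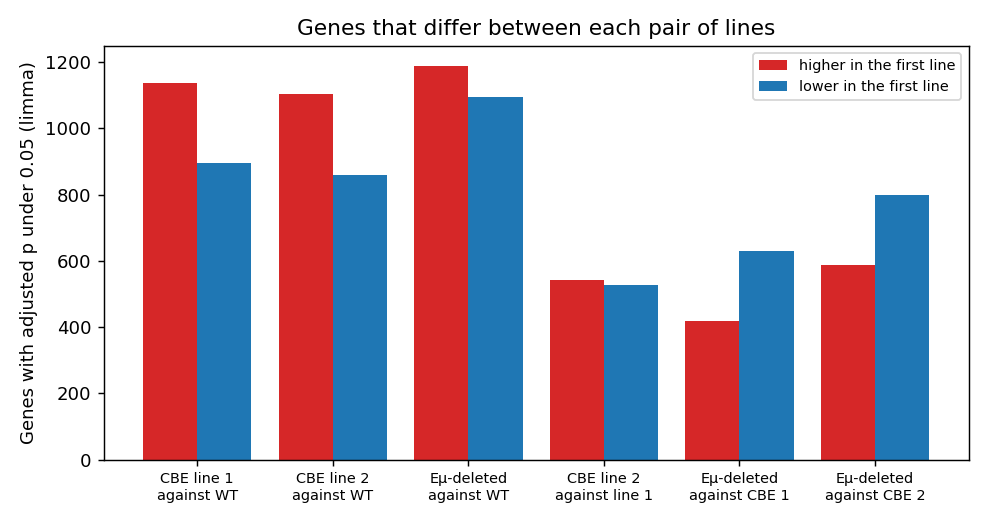
Bars give the number of genes with a limma adjusted p under 0.05, higher (red) or lower (blue) in the first-named line, for each of the 6 pairs of lines. Pairs with WT hold 1960 to 2284 genes and pairs of mutant lines 1051 to 1387.

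The Eµ-deleted line was also compared directly with the CBE lines, a comparison in which deletion and cell line cannot be separated. Between the Eµ-deleted line and the mean of the CBE lines, 1301 genes differed, 541 higher and 760 lower in the Eµ-deleted line. The excess of lower genes narrowed to 725 and 757 after quantile normalization and to 1149 and 1202 without Eµ-deleted replicate 1. Enpep (-5.32 (SE 0.13, adjusted p = 4.81e-06)), Nov (-6.13 (SE 0.28, adjusted p = 3.62e-05)) and Gfra1 (-4.42 (SE 0.08, adjusted p = 1.83e-06)) were lower in the Eµ-deleted line than in the CBE lines, and Gdpd3 (5.70 (SE 0.14, adjusted p = 4.81e-06)), Xlr (5.62 (SE 0.14, adjusted p = 4.81e-06)) and Mt2 (4.34 (SE 0.17, adjusted p = 2.36e-05)) were higher. These 6 genes were chosen after their values were seen, and each call held in all 8 leave-outs. Mc1r, low in the CBE lines, stood at 19.9 ± 3.76 FPKM in the Eµ-deleted line and 53.1 ± 6.27 in WT. Among integrated stress response genes, 1 of 24 passed the test (0 adjusted over the list alone) with a median of 0.81 (camera adjusted p = 0.00728; adjusted p = 0.946 with an estimated correlation). In the glycolysis list 1 was higher and 3 lower (1 and 6 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.00728; adjusted p = 0.946 with an estimated correlation). The sex-linked list was again called, with 4 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.000240, or 0.946 with an estimated correlation). By fry the sex-linked list passed the threshold (adjusted p = 0.000125), and the stress (0.608) and glycolysis lists (0.145) did not. The stress list was not called without CBE line 1 replicate 1 (median 0.24, adjusted p = 0.0566), nor the glycolysis list without Eµ-deleted replicate 2 (median -0.15, adjusted p = 0.516). The gene count was 2351 without Eµ-deleted replicate 1, 801 without replicate 2, and 718 and 723 without CBE line 2 replicate 1 or 2. Against each CBE line alone, an alternative chosen after seeing the data, 1051 genes differed from line 1 and 1387 from line 2.

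The 2 CBE lines share a genotype in the labels, and their difference measures how far lines of that genotype diverge. Cdkn2a stood at 22.1 ± 6.61 FPKM in line 1, 376 ± 6.97 in line 2 and 143 ± 0.573 in WT, a difference between the CBE lines of 4.06 (SE 0.21, adjusted p = 8.31e-05). In line 2 the homeobox gene Hoxa11 and its antisense neighbour Hoxa11os were at 11.7 ± 1.19 and 17.6 ± 2.89 FPKM, against line means of 0.00574 or less in the 3 other lines. Cpe, a prohormone-processing carboxypeptidase, and Kctd15 were at 9.84 ± 0.190 and 8.86 ± 0.319 in line 2 and listed at 0 in both libraries of line 1. The linker histone gene H1fx (4.55), Ica1 (3.29) and Ydjc (3.29) were higher in line 2 as well. Line 1 alone of the CBE lines expressed Aim2, a sensor of cytosolic DNA (-4.40), S100a11 (-4.28), Tmem98 (-4.05), Rnase4 (-3.65) and Cd300lh (-3.65) above 2 FPKM. Slamf6, a lymphocyte receptor gene (-3.80), Slc2a3, a glucose transporter gene (-3.40), and Ripk3, a kinase of necroptosis (-3.28), were lower in line 2.

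In total 1069 genes differed between CBE line 2 and line 1, 542 higher and 527 lower in line 2, with 214 and 176 at least 2-fold. Leaving aside the fit with the replicate number, this balance turned with median-of-ratios scaling (540 and 613), quantile normalization (579 and 655) and mean FPKM of 5 or more (143 and 226), and was 861 and 634 with no filter. It also turned without CBE line 1 replicate 1 (308 and 348) or either Eµ-deleted library (684 and 689). Histone genes lay lower in line 2: 18 of 56 fell and 0 rose (32 and 0 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 9.28e-12; adjusted p = 0.106 with an estimated correlation), although with genes of mean FPKM 5 or more alone the median was 0.02 (adjusted p = 0.599). Adhesion genes fell in 6 of 18 and rose in 0 (9 and 0 adjusted over the list alone), with Cd97 at -2.33, the galectin gene Lgals1 at -2.52 and S100a6 at -1.58 (camera adjusted p = 8.75e-07; adjusted p = 0.0884 with an estimated correlation). Interferon response genes fell in 5 of 30 (6 lower and 1 higher adjusted over the list alone), with Gbp2 at -1.18 and Gbp3 at -0.85 (camera adjusted p = 0.00127; adjusted p = 0.526 with an estimated correlation). Of p53 targets 1 rose and 4 fell (2 and 6 adjusted over the list alone), with Ccng1 at -1.51 (camera adjusted p = 0.0139; adjusted p = 0.992 with an estimated correlation). This p53 call was lost without CBE line 1 replicate 2 (median -0.21, adjusted p = 0.107). Pro-B and pre-B genes had 1 fall of 28 (0 adjusted over the list alone) at a median of -0.25 (camera adjusted p = 0.000557, or 0.562 with an estimated correlation). By fry, the adhesion (adjusted p = 0.000396) and histone lists (0.0124) passed the threshold downward. The interferon (0.0664), pro-B (0.0962) and p53 lists (0.282) did not. Trp53 (0.15 (SE 0.08, adjusted p = 0.336)), Ctcf (-0.09 (SE 0.15, adjusted p = 0.798)), Pax5 (0.40 (SE 0.16, adjusted p = 0.204)), Ebf1 (-0.05 (SE 0.15, adjusted p = 0.905)), Il7r (-0.46 (SE 0.38, adjusted p = 0.566)) and Xist (-0.14 (SE 0.25, adjusted p = 0.828)) did not pass the test between the CBE lines.

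The 15 remaining lists were not called by camera between the CBE lines. The pairs that follow give genes higher and lower in line 2, then the same adjusted over the list alone. They were 2 and 4 (4 and 6) for 16 later B cell genes, 2 and 0 (2 and 1) for 7 T lineage markers, 1 and 1 (1 and 1) for 23 immediate early genes, 2 and 0 (2 and 0) for 24 stress response genes, 1 and 1 (1 and 1) for 22 looping factors, 1 and 1 (0 and 1) for 26 early B factors, 0 and 2 (0 and 2) for 24 glycolysis genes, 0 and 1 (0 and 0) for 20 STAT5 targets, 1 and 0 (1 and 1) for 7 tumour suppressors, 0 and 0 (0 and 1) for 5 myeloid markers. The recombination, proliferation, cholesterol, sex-linked and housekeeping lists had 0 calls by limma, also adjusted over the list alone, and 3, 1, 0, 0 and 0 members at an unadjusted p under 0.05. The myeloid list had 1 at that level. Camera adjusted p for these 15 lists lay between 0.184 and 0.981. Jun (-1.24), the stress gene Stc2 (2.08), the cohesin release factor gene Wapal (1.03), Aldoc (-2.79) and Egln3 (-1.55) were among the members called. Outside these lists, the NK gene Klrd1 was called as well (0.95). The count of 1069 was 705 without either WT library, 656 without CBE line 1 replicate 1, 424 without CBE line 2 replicate 1 and 375 without CBE line 2 replicate 2.

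Whole chromosomes differed between lines. Genes of chromosome 19 were lower in the CBE-deleted lines than in WT, with a median log2 difference of -0.42 over 385 genes (181 lower, 21 higher; camera adjusted p = 4.21e-19; adjusted p = 0.0353 with an estimated correlation), and lower in the Eµ-deleted line with a median of -0.41 (157 lower, 20 higher; camera adjusted p = 1.30e-13; adjusted p = 0.0672 with an estimated correlation). Genes of chromosome 18 were lower in CBE line 2 than in line 1 by a median of -0.47 over 256 genes (102 lower, 9 higher; camera adjusted p = 6.47e-28; adjusted p = 0.0267 with an estimated correlation). Against WT, their median was 0.14 in line 1 (adjusted p = 0.667 with an estimated correlation), -0.30 in line 2 (adjusted p = 0.0975) and -0.30 in the Eµ-deleted line (adjusted p = 0.213). The first 43 genes (starts 3266352 to 24148135 in mm9) had medians of 0.55, 0.08 and 0.23 in line 1, line 2 and the Eµ-deleted line. The 5 later segments had medians of 0.0041 to 0.15, -0.41 to -0.29 and -0.50 to -0.31. Smaller differences between the CBE lines were called on chromosome 13 (median -0.15, adjusted p = 0.101 with an estimated correlation) and chromosome 15 (median -0.11, adjusted p = 0.104 with an estimated correlation). Leaving out the genes of chromosomes 18, 19, X and Y, an alternative chosen after seeing the data, gave 1919 genes for the CBE lines against WT, 1811 for the Eµ-deleted line and 859 for CBE line 2 against line 1.

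**Figure D4:**
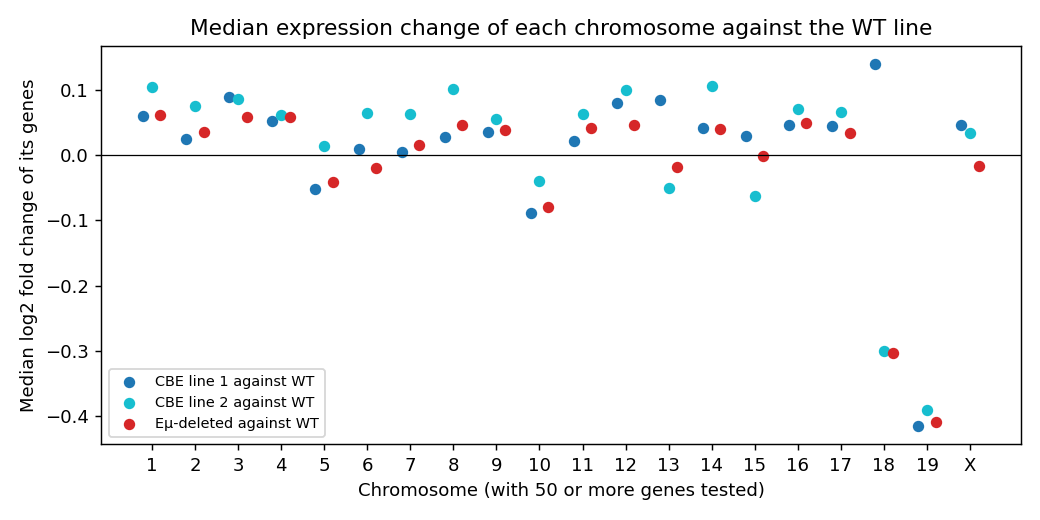
Points give the median log2 fold change of the genes tested on each chromosome, for CBE line 1, CBE line 2 and the Eµ-deleted line against WT. Chromosome 19 lies at -0.41, -0.39 and -0.41 in all 3 lines, and chromosome 18 at 0.14 in CBE line 1 and at -0.30 in CBE line 2 and in the Eµ-deleted line.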

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

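The test of a copy number change on chromosome 18 was chosen after the result was seen, and the tests of GC content and length were written before it. The results that follow stand out because the CBE lines, which share a genotype, differed from each other on the log2(FPKM + 1) scale, line 2 minus line 1. Genes were taken by limma's test, and lists and chromosomes by camera at the preset correlation, at an adjusted p under the 0.05 threshold.

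Of the named genes reported here, 60 differed between the CBE lines. The naming rule itself draws on this comparison, so neither this count nor its split describes all genes. Over all 10479 genes tested, 542 were higher and 527 lower in line 2. The 39 lower in line 2 were Aim2 (-4.40), S100a11 (-4.28), Tmem98 (-4.05), Slamf6 (-3.80), Rnase4 (-3.65), Cd300lh (-3.65), Slc2a3 (-3.40), Ripk3 (-3.28), Aldoc (-2.79), Cd74 (-2.61), Lgals1 (-2.52), Cd97 (-2.33), Cdkn1a (-1.91), S100a6 (-1.58), Egln3 (-1.55), Cyp4f18 (-1.54), Ccng1 (-1.51), Spp1 (-1.49), H2-Ab1 (-1.38), Jun (-1.24), Gbp2 (-1.18), Hist1h2be (-1.15), Hist1h2bb (-1.04), Hist1h2bl (-1.04), Hist1h2bg (-0.99), Zbp1 (-0.95), Hist1h4d (-0.94), Xbp1 (-0.92) and Gbp3 (-0.85), Blnk (-0.85), Zmat3 (-0.84), Igtp (-0.78), Gfi1 (-0.78), Ctnna1 (-0.74), Bcl2l1 (-0.71), Sox15 (-0.65), Phlda3 (-0.63), Lgals3bp (-0.52), Esco1 (-0.47). The largest adjusted p among them was 0.0452.

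The 21 higher in line 2 were Fam92a (0.38), Ngfrap1 (0.61), Irf4 (0.69), Cd28 (0.72), Nr4a1 (0.84), Tcf7 (0.90), Klrd1 (0.95), Wapal (1.03), Rnase12 (1.21), Vldlr (1.49), Tsnax (1.68), Stc2 (2.08), Cd22 (2.10), Ydjc (3.29), Ica1 (3.29), Kctd15 (3.30), Cpe (3.44), Hoxa11 (3.67), Cdkn2a (4.06), Hoxa11os (4.20), H1fx (4.55), with adjusted p up to 0.0432. For Cpe, Kctd15 and Hoxa11 the line 1 libraries are listed at 0, so their fitted differences depend on the pseudocount.

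Of these genes, 30 were called between the CBE lines in all 8 leave-outs. The other 30 lost the call without at least 1 library of WT or the CBE lines, with adjusted p of 0.0507 to 0.260 there: Bcl2l1, Blnk, Cd22, Cd28, Cd74, Cdkn1a, Ctnna1, Cyp4f18, Esco1, Fam92a, Gfi1, H2-Ab1, Hist1h2bb, Hist1h2be, Hist1h2bg, Hist1h2bl, Hist1h4d, Igtp, Irf4, Lgals3bp, Ngfrap1, Nr4a1, Phlda3, Sox15, Spp1, Tcf7, Vldlr, Xbp1, Zbp1 and Zmat3. By library left out, the losses were 15 without WT replicate 1, 15 without WT replicate 2, 22 without CBE line 1 replicate 1, 15 without CBE line 1 replicate 2, 25 without CBE line 2 replicate 1 and 29 without CBE line 2 replicate 2. In the other alternatives, the fold minimum aside, 20 of the 60 lost the call in at least 1, among them Rnase12, which held in all leave-outs, with a pseudocount of 5 (adjusted p = 0.0519).

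Gene lists called by camera between the CBE lines were, with their medians, histone genes (-0.61), adhesion genes (-0.42), pro-B genes (-0.25), interferon response genes (-0.22) and p53 targets (-0.19). None of the 5 calls held with an estimated correlation. By fry, the histone and adhesion lists passed the threshold, and the pro-B, interferon and p53 lists did not. Later B cell genes (median -0.58, camera adjusted p = 0.184) and stress response genes (median 0.49, camera adjusted p = 0.184) were not called. Chromosomes called in the same way had medians of -0.47 (chromosome 18), -0.15 (chromosome 13) and -0.11 (chromosome 15), and only that of chromosome 18 held with an estimated correlation.

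Genes of chromosome 18 were lower in CBE line 2 than in line 1 as a block. The median was -0.47 after a trend on GC content and transcript length was removed, which argues against such a bias as the whole cause. In all, 87.5% of the genes lay on the lower side. Each of 6 consecutive segments of the chromosome was lower, the one nearest 0 at -0.43, as a change in the number of copies of the whole chromosome would need, so such a change is a candidate explanation found and tested on the same data. No copy number was measured, and a regulatory difference between the lines stays open and untested.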

How the results depend on the processing

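The alternatives that leave out chromosomes 18, 19, X and Y or take the CBE lines singly were chosen after seeing the data. Of 206 named calls, 131 held in all 8 leave-outs, 157 in every other alternative but the fold minimum, 130 in all of these, and 0 reversed. The chromosome results kept their direction and their side of the threshold in the alternatives run on them other than the estimated correlation. The fold minimum was not run on them, and chromosomes 18 and 19 have no value where their genes are left out. The estimated correlation, added for them after seeing the data, ended the calls of chromosomes 19 (median -0.41) and 18 (-0.30) in the Eµ-deleted line against WT and of chromosomes 13 (-0.15) and 15 (-0.11) between the CBE lines. Where a setting moved a result, the cause was not tested, unless fewer genes, fewer libraries or a fold minimum made the change by construction. Simulated log2 changes of 0.5 between the CBE lines were recovered in 10.4% of the changed genes, none of them of low mean expression. As depth was not varied there, its part in this limit was not tested.

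Counts are given in the order CBE lines, CBE line 1, CBE line 2 and Eµ-deleted line against WT, CBE line 2 against line 1, Eµ-deleted against CBE lines, calls shared by both CBE lines, and calls shared by all 3 mutant lines. With mean FPKM of 5 or more they were 1247, 1056, 1023, 1304, 369, 535, 577 and 427. With a fold change of 2 or more they were 703, 758, 769, 751, 390, 421, 446 and 289. With only the libraries compared, CBE line 2 gave 3527 and the Eµ-deleted line 1255. Leaving out 1 library at a time gave 1022 to 2916, 903 to 2608, 950 to 2546, 890 to 3317, 375 to 1373, 718 to 2351, 550 to 1517 and 362 to 1036.

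With the replicate block, that is the replicate number as a covariate, counts were 3142, 3013, 3563, 1736, 2331, 1813 and 1322 from CBE line 1 on in the same order. Between the CBE lines this was 864 and 872 higher and lower in line 2, which turned the balance. The labels do not say what a number shares between lines. Deviations of same-numbered libraries correlated across genes with 0.279 to 0.502 over the 6 pairs of lines. Among the named genes, the called lists and the chromosome results, the block changed the call of 3 results, as Pax5 in the CBE lines (adjusted p = 0.0230) and Pax5 (adjusted p = 0.0207) and Ctcf (adjusted p = 0.0256) in the Eµ-deleted line passed the threshold.

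List calls moved as follows, as median log2 differences. With a pseudocount of 0.1, looping factors (0.34, adjusted p = 0.0538) and pro-B genes (0.30, adjusted p = 0.0538) in the Eµ-deleted line lost the call, as did pro-B genes with TPM (0.36, adjusted p = 0.0621). With mean FPKM of 5 or more, histone genes turned in the CBE lines (-0.15, adjusted p = 0.683), and between the CBE lines histone genes (0.0226, adjusted p = 0.599) and p53 targets (-0.17, adjusted p = 0.0767) lost the call. Quantile normalization ended the histone call in the CBE lines (0.22, adjusted p = 0.130). An estimated correlation leaves medians as they are and ended all 15 calls: against WT, proliferation 0.34 and histone 0.40 in the CBE lines, and looping 0.32, early B 0.28, pro-B 0.29, proliferation 0.23 and sex-linked 3.06 in the Eµ-deleted line. Between the CBE lines these were pro-B -0.25, p53 -0.19, interferon -0.22, adhesion -0.42 and histone -0.61, and between Eµ-deleted and CBE lines stress 0.81, glycolysis -0.40 and sex-linked 3.05. Of the 15 camera calls, only those of the sex-linked list and, between the CBE lines, of the adhesion and histone lists also passed the directional fry test.

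Leave-out medians ran from 0.27 to 0.46 for proliferation in the CBE lines. In the Eµ-deleted line against WT they ran from 0.19 to 0.33 for looping, 0.22 to 0.41 for early B, 0.22 to 0.39 for pro-B and 0.11 to 0.43 for proliferation. For p53 between the CBE lines the range was -0.36 to -0.18, and between Eµ-deleted and CBE lines 0.24 to 1.18 for stress and -0.70 to -0.15 for glycolysis. By camera, genes near the IgH locus in the Eµ-deleted line passed the threshold with no filter (0.20, unadjusted p = 0.0224) and median-of-ratios scaling (0.18, unadjusted p = 0.0464). They also passed it with quantile normalization (0.17, unadjusted p = 0.0469). The leave-out range was 0.13 to 0.32, and the side of the threshold also depended on Eµ-deleted replicate 2.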

Other observations

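The tests of copy number and of depth were chosen after the result was seen, as were the limits of 0.5 and 5 FPKM and the genes named here. The tests of GC content and length and of deleted segments were written before their values were computed, although the adjacency of Ctnna1 and Sil1 had been noticed.

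Some genes were switched between lines. In the WT line 28 genes lay under 0.5 FPKM in both libraries and at 5 or more in all 6 other libraries, against 0 such genes for CBE line 1, 1 for CBE line 2 (Slc2a3) and 6 for the Eµ-deleted line, among them Gfra1, Nov and Trpc6. The 28 included the transcription factor gene Runx3 (0.00598 at most in WT and at least 8.75 elsewhere), the methyltransferase gene Smyd2 (0 at most in WT and at least 19.8 elsewhere), the WD repeat gene Wdr11 (0.00398 at most in WT and at least 11.2 elsewhere) and the spectrin gene Sptbn1 (0.00666 at most in WT and at least 9.53 elsewhere), in FPKM. Expressed at 5 or more in a single line and under 0.5 in the rest were 8 genes in WT, 8 in CBE line 1, 9 in CBE line 2 and 6 in the Eµ-deleted line. Those of CBE line 2 included the neighbouring homeobox genes Hoxa10 and Hoxa11 with Hoxa11os. By limma, 842 genes set WT apart from each other line in 1 direction, against 228 for CBE line 1, 323 for CBE line 2 and 281 for the Eµ-deleted line.

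The 28 genes near 0 in WT lay on 15 chromosomes. Lower depth of the WT libraries is argued against, since the WT library with the fewest implied reads (33.1 M) had 97.7% of the median of the 6 other libraries (33.9 M). Deleted segments that reach the nearest expressed gene are argued against for most of the 28 genes. Of those neighbours 3.57% (2 of 56, Ctnna1 and Sil1) were near 0 in WT as well, against 0.389% of the 7204 genes expressed elsewhere. Ctnna1 and Sil1 are neighbours of each other, so a deleted segment that holds both stays open. Only genes expressed in all 6 other libraries counted as neighbours, so a segment that holds only less expressed neighbours would be missed. Rag1 and Rag2, which lie close together and were near 0 in WT, were not among the 28 genes and were not covered. Silencing of single genes in the WT line, or smaller deletions, may account for the pattern and were not tested, and line and genotype are confounded.

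Genes of chromosome 19 were lower in each mutant line than in WT. After a trend on GC content and length was removed the median nearest 0 was -0.39, which argues against such a bias as the whole cause. At least 81.6% of the genes lay on the lower side in each line. Each of 6 segments was lower in each line, the one nearest 0 at -0.30, so a difference in the number of copies of the whole chromosome is a candidate explanation, an extra copy in WT or a missing one in the 3 mutant lines. Among genes of mean FPKM 10 or more, the median ratio to WT was 0.745, 0.752 and 0.745 in CBE line 1, CBE line 2 and the Eµ-deleted line. No copy number was measured, and an effect of genotype stays open and untested.

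Replicate 2 differed from replicate 1 in the same direction in all 4 lines for the stress gene Ddit3 (log2 difference 1.86) and the transcription factor gene Cebpg (0.83) and the early response gene Ier2 (0.84), with 0 genes past the threshold by limma for the replicate number (lowest adjusted p = 0.0765) and 3274 at an unadjusted p under 0.05.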
